A study of Rattus norvegicus with 13 samples.

How the data were processed

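Bulk RNA of whole rat hearts was measured in 13 samples, in 3 tables of 1 time point each, all of whose 13 sample columns were used. Spatial data of the wider study were not used here. The values are expected counts as deposited: they are not negative, mostly whole with a minority of fractions, and not scaled between samples. The tool that made the expected counts is not given in the sources used here. The deposited notes list the mouse builds GRCm38 and mm10, which the rat gene names contradict. The 2-month table lists 25600 names and the tables of 6 and 8 months list 38600 identical names, of which 38599 match RefSeq symbols of the rat assembly GRCr8. There are 23019 names in both kinds of table. Positions of genes were not used.

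Expected counts were rounded to whole numbers. Each comparison used its own libraries alone, over names listed in all of its tables, with genes kept by filterByExpr, TMM scaling, and the two-sided quasi-likelihood F test of edgeR 4.0.16 (glmQLFit with the default of that version, its earlier method) in R 4.3.3. Adjusted p-values are Benjamini-Hochberg values with a threshold of 0.05. Fold changes are log2 values. Their standard error (SE) is the absolute log2 fold change divided by the square root of the F statistic of its test. It is an approximation that is unreliable where a group is near 0 counts. The p-values of single genes measure the spread between these samples. Those of the list tests by camera rest also on a preset correlation between genes. Those of Fisher's exact test treat genes as independent, which they are not. Levels in CPM are scaled by TMM within the 2-month table and across the tables of 6 and 8 months, except for the transgene levels, which are scaled by library total. Intervals have a confidence of 95%, are exact binomial, and like the floor of 3 counts cover counting error only. Library totals ran from 4.70 to 11.3 M counts, so that 3 counts are 0.266 CPM in the deepest library and 0.639 CPM in the shallowest.

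Gene lists (40, with 1154 entries, on heart function, stress, metabolism, immune response and markers of other cell types and tissues) were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2, a preset correlation of 0.01 and at least 5 tested members, with Benjamini-Hochberg adjustment over the lists. An estimated correlation and fry were alternatives. Of 11 lists that passed at 2 months 0 passed with the estimated correlation, of 15 at 6 months 2 did (immediate early and heat shock), and of 10 in ST hearts of 8 against 6 months 1 did (immediate early). In simulated counts with the immediate early genes raised 2-fold, the estimated correlation missed that list at 2 months (adjusted p = 0.0575). There fry found it (adjusted p = 0.0397), as did camera. At 6 months and at 8 against 6 months the estimated correlation found it too. The simulated genes varied independently of each other, whereas the estimated correlation of this list at 2 months was 0.369 in the real data. The simulation thus cannot tell how the tests fare with correlated genes. In the real data fry, too, called 0 lists at 2 months. A lost call there does not show that a list did not change, and a call by camera alone does not show that it did. The comparisons, tests, gene lists, first set of alternatives and the rule for named genes were chosen before the data were examined.

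The rule for named genes took, for each comparison of ST with WT, the 8 largest and 8 smallest log2 fold changes among genes past the threshold with a mean log2 CPM of at least 1 and no overlap of the groups. It added up to 4 members with the smallest p of each list with a member past the threshold, a fixed set of heart genes and the transgene. Comparisons between ages took fewer by the same rule, and names that are locus or clone identifiers were passed over. The text names a selection of the genes that the rule gives, made after their values were seen; any gene outside the rule is said to be so. Some genes that the rule gives are not reported here, and counts of named genes leave them out.

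Alternatives were other size factors, scaling by library size only, no filter or a stricter filter of 5 CPM, DESeq2 1.42.0, limma-voom, a block for the replicate number, a fit over all groups, a fold change of at least 1.5, leaving out mitochondrially encoded and haemoglobin genes, and leaving out each library in turn. The 13 mitochondrially encoded protein genes are listed at 2 months alone, where they held 14.8% to 18.1% of counts. In comparisons with later hearts that alternative therefore left out none of them. Alternatives for normalized values did not apply. The whole procedure was tested on simulated data with known changes: at 2 months it recovered 28.4% of 1.5-fold, 74.2% of 2-fold and 93.8% of 4-fold changes, with 9.22% of 141 calls false, and at 6 months 68.7%, 92.3% and 100%, with 8.15% of 184 calls false. The false share was thus above the nominal 5% in both.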

Results

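Total RNA of rat heart tissue was sequenced in bulk in 13 samples. Control hearts are labelled WT. Hearts of the sonogenetic group, called ST here, received an adeno-associated virus carrying MscL-G22S, a variant of a bacterial mechanosensitive channel, with the fluorescent protein mCherry, under the promoter of Tnnt2 (cardiac troponin T), which is active in heart muscle cells. There were 2 WT and 2 ST hearts at 2 months, 3 WT and 3 ST hearts at 6 months, and 3 ST hearts with no WT group at 8 months. The sample titles do not say whether these months are the age of the rats or the time since the virus was given. Throughout the text, age stands for the labelled time point only. Whether ultrasound was applied before harvest is not stated in the labels. Library totals ran from 6.54 to 11.3 M counts at 2 months, from 6.72 to 8.49 M at 6 months and from 4.70 to 5.57 M at 8 months.

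The transgene was found in every ST heart. MSCL_G22S had 0 counts in every WT library, which allows up to 0.459 CPM (counts per M counts) in the shallowest of them. Its level in ST hearts, scaled by library total alone, was 11.1 ± 0.141 CPM at 2 months (SD, n = 2), 165 ± 65.3 CPM at 6 months (SD, n = 3) and 152 ± 32.7 CPM at 8 months (SD, n = 3). With a floor of 3 counts over the WT group, MSCL_G22S was at least 56.6-fold higher in ST hearts at 2 months and at least 1180-fold higher at 6 months. mCherry, listed in the 2-month table alone, had 472 counts in ST and 1 count in WT hearts, a ratio of 363 with a 95% counting interval from 64.8 to 14400. The tables of 2 and 6 months list different gene names, and only the totals of 2 months include mitochondrially encoded protein genes. The levels of 2 months and later therefore stand side by side without a claim of a rise.

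The first comparison asks how ST hearts differed from WT hearts at 2 months (n = 2 and 2). Nuclear receptors of the immediate early response were higher in ST hearts: Nr4a3 went from 3.24 ± 0.149 to 47.8 ± 4.32 CPM (SD, n = 2 each; log2 fold change 3.87, SE 0.197) and Nr4a1 from 6.18 ± 2.76 to 45.2 ± 6.56 CPM (2.81, SE 0.223). Lower genes included members of antigen presentation (10 of 22 tested) and of the interferon response (14 of 34, with 1 higher): the peptide transporter Tap1 (-1.62, SE 0.191), the transcriptional activator of class I genes Nlrc5 (-1.30, SE 0.177) and the antiviral gene Mx1 (-2.34, SE 0.374). The calls of these lists by camera were lost with an estimated correlation, at adjusted p = 0.619 and adjusted p = 0.521. Pdk4, a kinase that restrains glucose oxidation, rose by 1.92 (SE 0.136) and Ppargc1a, a coactivator of mitochondrial biogenesis, by 1.31 (SE 0.128). By the edgeR test, 582 of 12121 genes differed at an adjusted p of 0.05, 327 higher and 255 lower in ST hearts, and 2259 genes had an unadjusted p under 0.05. The ST and WT libraries did not overlap in 48.9% of genes, where chance gives 33.3%. The count fell to 271 without WT replicate 1 and rose to 2013 without ST replicate 2. DESeq2 gave 355 genes.

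Largest changes at 2 months included Tmem63c, which rose by 4.22 (SE 0.323) from 0.703 to 13.6 CPM, Folr2, a folate receptor of macrophages, which rose by 3.59 (SE 0.524), and Ifit1, an interferon-induced gene, which rose by 3.62 (SE 0.421). Msln, a mesothelial surface protein, had 2 counts in WT and 68 in ST hearts, a ratio of 26.1 with an interval from 6.96 to 220. The ST hearts differed in Msln, at 5.06 and 1.29 CPM, and without ST replicate 1 the gene was below the filter. Mgst3l1, whose name marks a possible gene copy and whose reads may therefore be shared, had 3 and 63 counts, a ratio of 16.1 with an interval from 5.28 to 80.4. Lower were Pbld1 (-4.02, SE 0.518) and Efcab6 (-2.93, SE 0.174). So were the axonemal dyneins Dnah7 (-2.61, SE 0.343) and Dnah5 (-2.49, SE 0.236), the endothelial gene Esm1 (-2.54, SE 0.432), the lipase-related gene Pnpla3 (-2.31, SE 0.265) and the transporter Slc47a1 (-2.29, SE 0.350).

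Among the 22 antigen presentation genes tested, 10 were lower and 0 higher (14 lower when adjusted over the list alone). The median log2 fold change was -0.73. RT1-A1, a class I gene whose reads may be shared with its close copies, fell by 1.35 (SE 0.140). The camera test of the list gave an adjusted p = 4.11e-16, and adjusted p = 0.619 with an estimated correlation. Of 34 interferon response genes 14 were lower and 1, Ifit1, was higher (24 lower and 1 higher when adjusted over the list alone; median -0.82), with Ifi27 at -1.03 (SE 0.168) and Bst2 at -0.98 (SE 0.169). Its camera test gave an adjusted p = 6.53e-15, and adjusted p = 0.521 with an estimated correlation. Markers of T, B and NK cells moved with these lists, at a median of -0.90 over 5 tested genes of which 0 passed, while 23 macrophage and monocyte markers had a median of 0.07.

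Of 30 immediate early genes 6 were higher and 1 was lower (7 higher and 1 lower when adjusted over the list alone; median 0.16, adjusted p = 0.00101, and adjusted p = 0.873 with an estimated correlation). Klf10 rose by 1.72 (SE 0.169) and Fosl2 by 1.08 (SE 0.136). Mesothelial and epicardial markers were higher for 4 of 8 genes (4 when adjusted over the list alone; median 0.84, adjusted p = 3.89e-05, and adjusted p = 0.619 with an estimated correlation), with Aldh1a1, a retinoic acid enzyme, at 0.88 (SE 0.133). Erythroid genes were higher for 2 of 7 (3 when adjusted over the list alone; median 0.63, adjusted p = 0.00752, and adjusted p = 0.708 with an estimated correlation), among them the haemoglobin gene Hba-a2 at 1.30 (SE 0.155). Without ST replicate 2 the erythroid list had an adjusted p = 0.195.

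Cell cycle genes were lower for 3 of 25 (6 when adjusted over the list alone; median -0.78, adjusted p = 0.000154, and adjusted p = 0.708 with an estimated correlation). Mki67, a proliferation marker, fell by 1.18 (SE 0.223) and Top2a, a topoisomerase of dividing cells, by 1.12 (SE 0.280), the latter with an adjusted p = 0.431 without WT replicate 1 and 0.175 in DESeq2. The fetal and stress gene list, which holds genes that the diseased heart turns back on, was lower for 4 and higher for 1 of 17 (4 lower and 2 higher when adjusted over the list alone; median -0.10, adjusted p = 0.02, and adjusted p = 0.873 with an estimated correlation). Its members included the natriuretic peptide gene Nppb (-1.38, SE 0.151), skeletal actin Acta1 (-1.33, SE 0.181), the calcineurin regulator Rcan1 (-1.15, SE 0.133) and the stretch-responsive gene Ankrd1 (-0.95, SE 0.151). This list lost its call without WT replicate 1 (adjusted p = 0.357) and without ST replicate 2 (adjusted p = 0.15).

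Ventricular markers were lower for 3 of 11 (4 lower and 1 higher when adjusted over the list alone; median -0.16, adjusted p = 0.0219, and adjusted p = 0.834 with an estimated correlation), with the patterning factors Irx3 at -1.64 (SE 0.2) and Irx5 at -1.39 (SE 0.190). Sarcomere genes were lower for 2 of 28 (2 when adjusted over the list alone; median -0.22, adjusted p = 0.000441, and adjusted p = 0.708 with an estimated correlation), with the myosin gene Myh7b at -0.56 (SE 0.129). Oxidative phosphorylation genes were lower for 1 of 70, the complex I gene Ndufb8 at -0.60 (SE 0.166), and 0 when adjusted over the list alone (median -0.13, adjusted p = 0.000441, and adjusted p = 0.873 with an estimated correlation). Without ST replicate 1 this list had an adjusted p = 0.11. Genes with very long messenger RNAs had a median of 0.15 in this comparison, with 14 of 58 below 0. Unfolded protein and integrated stress genes were lower for 1 of 25, the chaperone gene Dnajb11 at -0.56 (SE 0.142), and 1 lower and 1 higher when adjusted over the list alone (median -0.16, adjusted p = 0.00944, and adjusted p = 0.708 with an estimated correlation). That list had an adjusted p = 0.114 without WT replicate 1 and 0.0786 without ST replicate 2.

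Single genes of lists that did not pass as a whole also differed at 2 months. The clock genes Dbp (-0.64, SE 0.141) and Nr1d1 (-0.63, SE 0.127) were lower, the heat shock gene Hspa1a was higher (0.58, SE 0.146) and Hspb1 lower (-0.48, SE 0.130), the matrix protein gene Thbs1 was higher (1.77, SE 0.201) and so was the channel gene Trpv4 (1.97, SE 0.344). Without WT replicate 1 the adjusted p was 0.0754 for Dbp, 0.0544 for Nr1d1, 0.381 for Hspa1a, 0.549 for Hspb1, 0.2 for Ndufb8, 0.32 for Myh7b and 0.455 for Dnajb11. Without WT replicate 2 it was 0.0787 for Dbp, 0.112 for Nr1d1, 0.121 for Hspa1a, 0.146 for Hspb1, 0.0571 for Ndufb8, 0.0702 for Myh7b and 0.0957 for Dnajb11. Without ST replicate 1 it was 0.0562 for Hspb1 and 0.151 for Ndufb8. In DESeq2 it was 0.105 for Dnajb11 and 0.0727 for Hspa1a. Without the mitochondrially encoded and haemoglobin genes it was 0.0508 for Ndufb8. Of the heart genes named in advance, Nppa, Myh7, Tnnt2, Myh6, Atp2a2, Ryr2, Gja1, Piezo1 and Col1a1 did not pass, with Tnnt2 at -0.36 (SE 0.142) and Piezo1 at -0.08 (SE 0.139). The single-library spread was wide for Nppa (-0.49, SE 0.393) and Myh7 (-0.84, SE 0.330): without WT replicate 2 they stood at -1.14 and -1.41, and without ST replicate 1 at -1.22 and -1.36, each past the threshold. Without WT replicate 1 Nppa stood at 0.78 with an adjusted p = 0.0401. With a block for the replicate number Myh7 stood at -0.72 with an adjusted p = 0.0114. Without a filter on low counts Nppa (-0.48, adjusted p = 0.0165) and Myh7 (-0.84, adjusted p = 1.61e-08) passed, and in one fit over all groups Tnnt2 did (-0.35, adjusted p = 0.0108). Tnnt2 passed without ST replicate 2, at -0.46 with an adjusted p = 0.0272.

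At 6 months the comparison of ST with WT hearts (n = 3 and 3) gave higher levels of immediate early and heat shock genes. Fos, an immediate early transcription factor, went from 1.38 ± 0.344 to 60.9 ± 3.29 CPM (SD, n = 3 each; log2 fold change 5.46, SE 0.146), Nr4a1 from 7.42 ± 1.11 to 198 ± 20.8 CPM (4.74, SE 0.119) and Thbs1 from 12.3 ± 0.989 to 466 ± 82.4 CPM (5.24, SE 0.143). The slow myosin heavy chain gene Myh7, a marker of the stressed ventricle in rats, rose by 2.51 (SE 0.114) and its fast counterpart Myh6 fell by 0.46 (SE 0.060). The clock output gene Dbp went from 215 ± 5.14 to 27.9 ± 1.18 CPM (-2.94, SE 0.073). By the edgeR test 5305 of 13253 genes (40%) differed, 2643 higher and 2662 lower, and 2648 of them by at least 1.5-fold. Counts of list members at this age that come near this share are no mark of their list. With scaling by library size only, 1731 genes were higher and 3714 lower, and the median of all genes moved by -0.115. Libraries of ST and WT did not overlap in 51.7% of genes, where chance gives 10%.

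**Figure D1:**
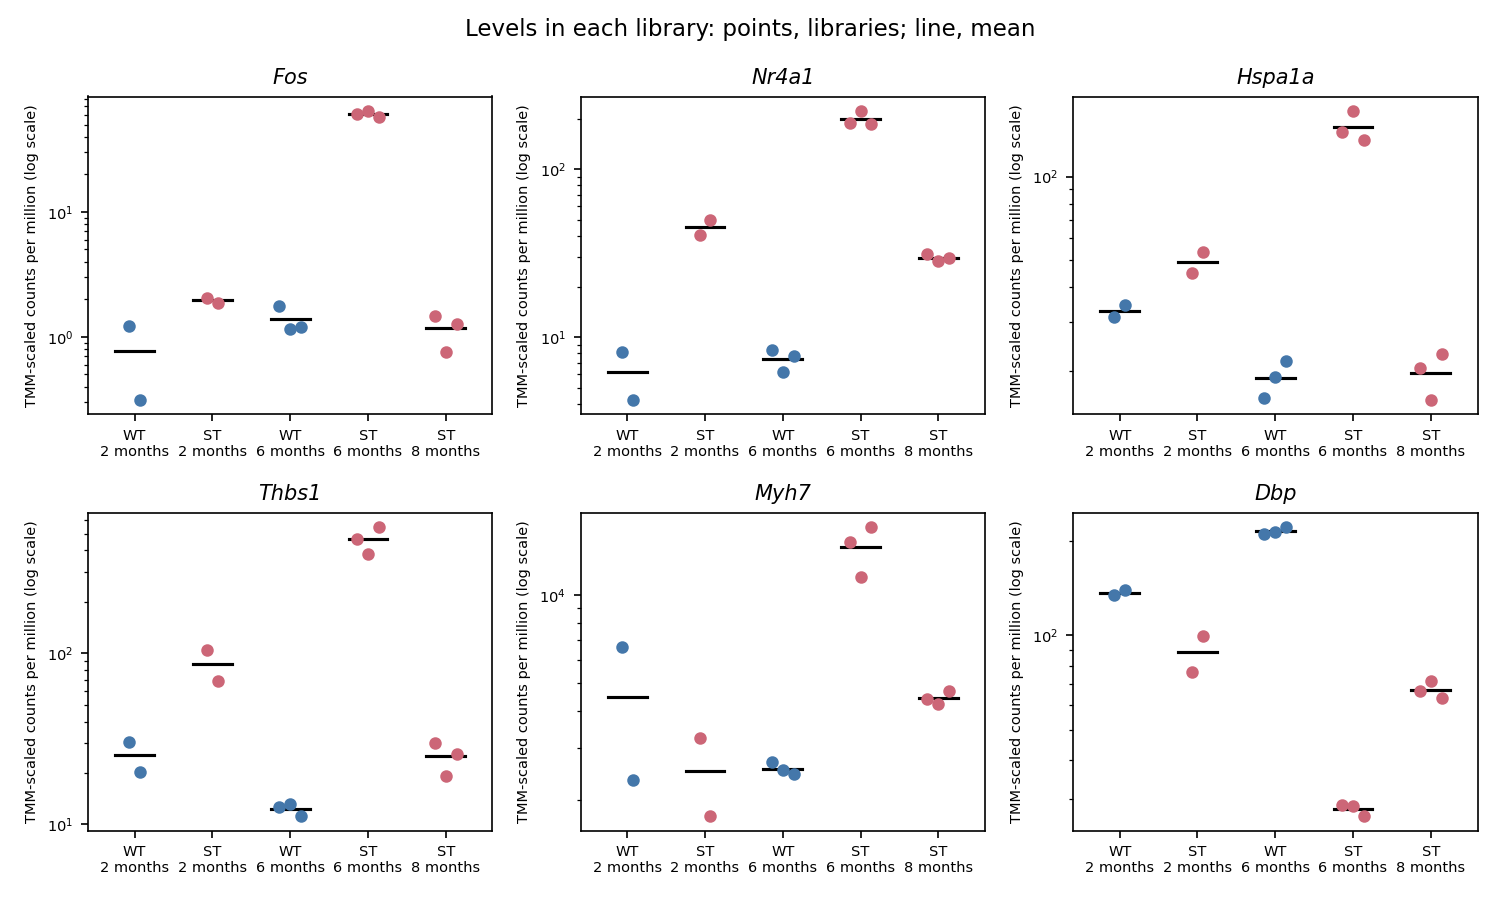
TMM-scaled CPM on a log axis for 6 genes in 5 groups; each point is 1 library and each line the mean of its group, with scaling done within the 2-month table and across the 6-month and 8-month tables. The 3 ST hearts of 6 months lie between 57.7 and 64.2 CPM for Fos and between 26.5 and 28.7 CPM for Dbp, apart from the WT hearts of that age.

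Immediate early genes were higher for 30 of 33 and lower for 0 (30 when adjusted over the list alone; median 2.21, adjusted p = 3.09e-24, and adjusted p = 0.0162 with an estimated correlation). Nr4a3 rose by 5.89 (SE 0.167), Egr1, a zinc finger transcription factor, by 4.67 (SE 0.132), and Ccn1, a matrix signalling protein, by 2.75 (SE 0.119). Heat shock genes were higher for 24 of 26 (24 when adjusted over the list alone; median 0.78, adjusted p = 4.55e-14, and adjusted p = 0.0162 with an estimated correlation), with Hspa1a at 2.99 (SE 0.122), Hspb1 at 1.58 (SE 0.096) and Hsp90aa1 at 1.5 (SE 0.073). Fetal and stress genes were higher for 18 of 20 (18 when adjusted over the list alone; median 1.67, adjusted p = 1.35e-12, and adjusted p = 0.147 with an estimated correlation). Beside Myh7 they included Nppb (3.87, SE 0.341), Rcan1 (2.59, SE 0.081), the intercalated disc gene Xirp1 (2.08, SE 0.079) and Ankrd1 (1.34, SE 0.088). The natriuretic peptide gene Nppa stood at 2.79 (SE 0.757, adjusted p = 0.0118), and its adjusted p was 0.0549 without WT replicate 2, 0.0577 without ST replicate 3 and 0.0668 in limma-voom.

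Unfolded protein and integrated stress genes were higher for 15 and lower for 1 of 27 (17 and 1 when adjusted over the list alone; median 0.36, adjusted p = 0.000164, and adjusted p = 0.327 with an estimated correlation), with the transcription factor Atf4 at 1.24 (SE 0.065) and its target Ppp1r15a at 1.69 (SE 0.081). Inflammatory genes were higher for 11 of 20 (12 when adjusted over the list alone; median 0.57, adjusted p = 0.000461, and adjusted p = 0.147 with an estimated correlation), among them the cytokine signalling inhibitor Socs3 (2.96, SE 0.335) and the chemokine Ccl2 (2.54, SE 0.324). Mechanosensing genes were higher for 14 and lower for 4 of 31 (14 and 4 when adjusted over the list alone; median 0.10, adjusted p = 0.00744, and adjusted p = 0.177 with an estimated correlation). Trpv4 rose by 2.64 (SE 0.217) and the stretch-activated channel gene Piezo1 by 0.55 (SE 0.124). Oxidative stress genes were higher for 11 and lower for 6 of 33 (13 and 7 when adjusted over the list alone; median 0.12, adjusted p = 0.0302, and adjusted p = 0.625 with an estimated correlation), with the metallothionein gene Mt2A at 3.52 (SE 0.302).

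Sarcomere genes were higher for 15 and lower for 5 of 28 (16 and 5 when adjusted over the list alone; median 0.20, adjusted p = 0.0129, and adjusted p = 0.625 with an estimated correlation). Myot rose by 3.00 (SE 0.135) and Flnc by 1.48 (SE 0.075), both of the Z-disc, while Tcap, which caps titin, fell by 0.96 (SE 0.074). Oxidative phosphorylation genes were higher for 17 of 79, and for 5 when adjusted over the list alone (median 0.15, adjusted p = 1e-04, and adjusted p = 0.725 with an estimated correlation), with Ndufa12 at 0.49 (SE 0.081) and Cox7a1 at 0.84 (SE 0.160). Glycolysis and glucose use genes were higher for 16 and lower for 5 of 37 (17 and 5 when adjusted over the list alone; median 0.13, adjusted p = 0.00906, and adjusted p = 0.625 with an estimated correlation), with Pfkfb2, which makes an activator of glycolysis, at 1.19 (SE 0.085).

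Markers of other cell types moved as well. Smooth muscle and pericyte markers were higher for 12 of 20 (12 when adjusted over the list alone; median 0.30, adjusted p = 0.000742, and adjusted p = 0.625 with an estimated correlation), with Acta2 at 1.27 (SE 0.153) and Mcam at 1.09 (SE 0.121). Erythroid genes were higher for 8 of 12 (9 when adjusted over the list alone; median 0.60, adjusted p = 0.000742, and adjusted p = 0.502 with an estimated correlation), with the anion exchanger Slc4a1 at 2.99 (SE 0.142). Endothelial markers were higher for 12 and lower for 3 of 24 (14 and 3 when adjusted over the list alone; median 0.27, adjusted p = 0.0177, and adjusted p = 0.725 with an estimated correlation), with the junction gene Cldn5 at 1.58 (SE 0.126) and the receptor gene Aplnr at -1.57 (SE 0.115). The endothelial list had an adjusted p = 0.0646 without WT replicate 2 and 0.0556 without ST replicate 3. Mesothelial and epicardial markers were lower for 5 and higher for 1 of 8 (5 and 1 when adjusted over the list alone; median -1.35, adjusted p = 0.0356, and adjusted p = 0.625 with an estimated correlation), with Ezr at -1 (SE 0.087), Aldh1a1 at -1.70 (SE 0.165) and Msln at -3.19 (SE 0.631). That list had an adjusted p = 0.0511 without WT replicate 2, 0.0637 without WT replicate 3 and 0.11 with scaling by library size only.

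Antigen presentation genes were lower for 13 of 26 and higher for 0 (14 lower when adjusted over the list alone; median -0.26, adjusted p = 0.000374, and adjusted p = 0.327 with an estimated correlation). RT1-CE5 fell by 1.09 (SE 0.068) and RT1-Da by 0.84 (SE 0.114), both with reads that may be shared between close copies. Markers of T, B and NK cells had a median of -0.47 over 8 tested genes, of which 1 was lower. Circadian clock genes were lower for 10 and higher for 8 of 23 (10 and 8 when adjusted over the list alone; median -0.13, adjusted p = 0.163), with Bhlhe41 at -2.66 (SE 0.114) and Nr1d1 at -1.73 (SE 0.088). Genes of fatty acid oxidation were higher for 13 and lower for 9 of 42 (14 and 9 when adjusted over the list alone; adjusted p = 0.414), including Pdk4 (2.98, SE 0.127), the lipase inhibitor Angptl4 (2.87, SE 0.185) and the uncoupling protein gene Ucp3 (2.09, SE 0.145). Extracellular matrix genes were higher for 13 and lower for 9 of 34 (13 and 9 when adjusted over the list alone; adjusted p = 0.599). The fibrillar collagen genes Col1a1 (-1.16, SE 0.106) and Col3a1 (-1.07, SE 0.096) were among the lower ones.

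The genes with the largest changes at 6 months beside those above were Pck1, an enzyme of gluconeogenesis (6.30, SE 0.546), the hyaluronan synthase Has1 (5.51, SE 0.245) and the acetylcholine receptor subunit Chrna1 (5.28, SE 0.493). Ifit1 had 1 count in WT and 113 in ST hearts, a ratio of 106 with an interval from 18.7 to 4230, and Slc47a1 had 3 and 128, a ratio of 40.1 with an interval from 13.4 to 197. Adh1c, an alcohol dehydrogenase, had 251 counts in WT and 3 in ST hearts, a ratio of 89.1 with an interval from 30.1 to 435. Lower genes also included Sec14l5 (-3.65, SE 0.354), Folr2 (-3.44, SE 0.379), Klhl33 (-3.20, SE 0.123), the DNA demethylase Tet1 (-3.04, SE 0.167) and Frem2 (-2.96, SE 0.398). The cell cycle inhibitor Cdkn1a rose by 2.57 (SE 0.089) and the vascular growth factor Vegfa by 1.06 (SE 0.074). The heart-muscle gene Lrrc10 fell by 2.58 (SE 0.083) and the ventricular factor Irx4 by 1.83 (SE 0.141). Of the heart genes named in advance, Gja1 (0.66, SE 0.086) and Tnnt2 (0.27, SE 0.055) were higher, while Atp2a2 (-0.06, SE 0.056) and Ryr2 (0.13, SE 0.068) did not pass. Ryr2 passed without WT replicate 2, at 0.20 with an adjusted p = 0.0474, and Atp2a2 with scaling by library size only, at -0.18 with an adjusted p = 0.0157. Without WT replicate 1 and ST replicate 2, a setting chosen after seeing the data, Atp2a2 stood at -0.15 with an adjusted p = 0.00044.

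**Figure D2:**
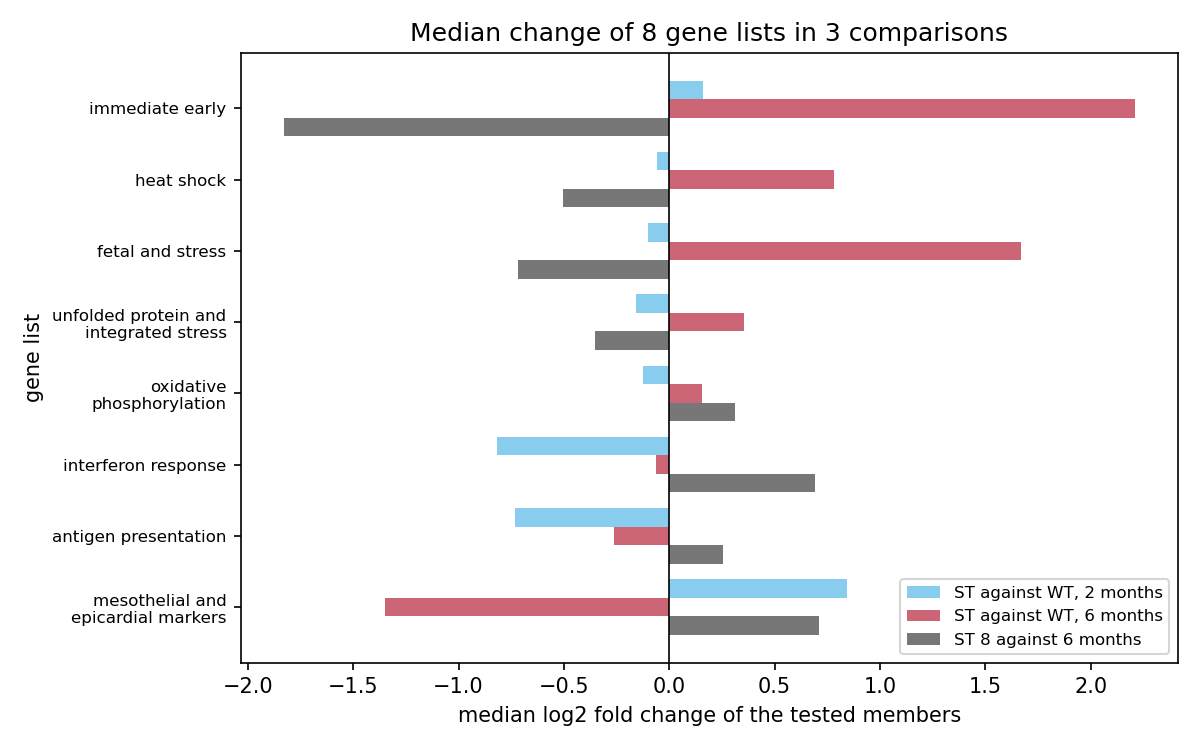
Median log2 fold change of the tested members of 8 gene lists, as bars, in 3 comparisons. Immediate early genes stand at 2.21 for ST against WT at 6 months and at -1.83 for ST at 8 against 6 months.

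The ST effect was then compared between ages as a difference of differences over names shared by both tables. It differed for 2813 of 12659 genes by the edgeR test, with a more positive effect at 6 months for 1296 and a more negative one for 1517, and for 1558 genes without WT replicate 1 of 2 months. With scaling by library size only the split was 1004 and 1896. Egr1 (5.19, SE 0.254), Rcan1 (3.73, SE 0.145) and Nppb (5.24, SE 0.458) had a more positive effect at 6 months, and Klf10 (-1.88, SE 0.171) a more negative one. Of 11450 genes tested at both ages, 145 were higher in ST hearts both times against 63.2 by chance (odds ratio 3.59, two-sided Fisher's exact test p = 4.19e-26) and 92 were lower both times against 46.8 (odds ratio 2.66, p = 6.95e-12, the same exact test). In opposite directions, 59 were higher at 2 and lower at 6 months against 61.9 by chance, and 59 were lower and then higher against 47.7. The exact tests treat genes as independent, which they are not, so their p-values are too small by an unknown amount. DESeq2 gave 138 shared genes in all, against 237. Across genes, which are not independent replicates, the fold changes of the 2 ages had a Pearson's r of 0.136 and a Spearman's rho of 0.0302.

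ST hearts at 8 months were compared with ST hearts at 6 months (n = 3 and 3), since the labels list no WT hearts of 8 months. Immediate early genes were lower at 8 months: Fos fell to 1.17 ± 0.375 CPM (SD, n = 3; log2 fold change -5.70, SE 0.166) and Nr4a1 to 29.7 ± 1.47 CPM (-2.74, SE 0.093). The matrix protein gene Thbs1 fell to 25 ± 5.48 CPM (-4.22, SE 0.152). Myh7 fell by 1.71 (SE 0.101), to 4440 ± 224 CPM. Lrrc10 rose by 2.47 (SE 0.064) and the collagen gene Col3a1 by 1.08 (SE 0.082). By the edgeR test 5115 of 12931 genes (39.6%) differed, 2464 higher and 2651 lower, against 3072 higher and 2140 lower with scaling by library size only. List counts near this share are again no mark of their list. Libraries did not overlap in 51% of genes, where chance gives 10%. Age, harvest and any difference in preparation between the tables cannot be told apart here.

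At 8 against 6 months, immediate early genes were lower for 30 of 32 (30 when adjusted over the list alone; median -1.83, adjusted p = 9.63e-27, and adjusted p = 0.0307 with an estimated correlation), Ccn1 among them at -1.70 (SE 0.138). Heat shock genes were lower for 19 and higher for 3 of 26 (19 and 3 when adjusted over the list alone; median -0.51, adjusted p = 2.59e-09, and adjusted p = 0.146 with an estimated correlation), with Hspa1a at -2.93 (SE 0.127) and Dnajb4 at -1.54 (SE 0.064). Unfolded protein and integrated stress genes were lower for 19 of 27 (20 when adjusted over the list alone; median -0.35, adjusted p = 5.92e-07, and adjusted p = 0.146 with an estimated correlation), with Atf4 at -1.21 (SE 0.068) and Ppp1r15a at -1.91 (SE 0.088). Fetal and stress genes were lower for 12 and higher for 1 of 20 (13 and 1 when adjusted over the list alone; median -0.72, adjusted p = 3.44e-06, and adjusted p = 0.401 with an estimated correlation), with Xirp1 at -2.36 (SE 0.081). Mechanosensing genes were lower for 17 and higher for 6 of 32 (17 and 6 when adjusted over the list alone; median -0.26, adjusted p = 0.0131, and adjusted p = 0.146 with an estimated correlation), with Trpv4 at -2.48 (SE 0.249). Autophagy and proteolysis genes were lower for 13 and higher for 4 of 32 (15 and 4 when adjusted over the list alone; median -0.16, adjusted p = 0.0134, and adjusted p = 0.146 with an estimated correlation), with the muscle ubiquitin ligase genes Fbxo40 (-0.64, SE 0.066) and Trim54 (-0.40, SE 0.059).

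Macrophage and monocyte markers were lower at 8 months for 8 and higher for 1 of 24 (8 and 1 when adjusted over the list alone; median -0.32, adjusted p = 0.0253, and adjusted p = 0.521 with an estimated correlation), with Mrc1 at -1.48 (SE 0.132) and F13a1 at -1.81 (SE 0.209). Without ST replicate 1 of 6 months that list had an adjusted p = 0.0515, and without ST replicate 2 of 6 months 0.0544. Oxidative phosphorylation genes were higher for 60 and lower for 1 of 79 (62 and 2 when adjusted over the list alone; median 0.31, adjusted p = 2.8e-17, and adjusted p = 0.146 with an estimated correlation), with Uqcrb at 0.60 (SE 0.053) and Atp5pf at 0.53 (SE 0.052). Genes with very long messenger RNAs moved the other way in this comparison, with 34 of 58 lower, 4 higher and a median of -0.31. Interferon response genes were higher for 24 and lower for 2 of 37 (25 and 2 when adjusted over the list alone; median 0.69, adjusted p = 1.66e-06, and adjusted p = 0.146 with an estimated correlation), with Mx2 at 0.98 (SE 0.086) and Ifi27 at 0.93 (SE 0.096). Antigen presentation genes were higher for 10 and lower for 1 of 25 (12 and 2 when adjusted over the list alone; median 0.25, adjusted p = 0.0131, and adjusted p = 0.168 with an estimated correlation). RT1-CE5 rose by 0.85 (SE 0.079), RT1-CE10 by 2.32 (SE 0.244) and RT1-CE16 by 4.54 (SE 0.120). Each has reads that may be shared between close copies. RT1-N2, with the same limit, had 3 counts at 6 and 153 at 8 months, a ratio of 76.0 with an interval from 25.5 to 373.

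Lnc-hc was at least 47.7-fold higher at 8 than at 6 months, from a floor of 3 counts over the group, and C15h13orf42 at least 17-fold lower. Dnah7 had 110 counts at 6 and 2 at 8 months, a ratio of 36.9 with an interval from 9.97 to 308. Has1 (-6.01, SE 0.290) and Pck1 (-5.13, SE 0.511) were lower, and the butyrophilin-like gene Btnl9 (3.21, SE 0.152) and Rps10l6, a possible copy of a ribosomal protein gene (6.99, SE 0.324), were higher. The clock genes Nr1d1 (1.17, SE 0.070) and Per2 (-1.99, SE 0.089) moved in opposite directions. Of the 2629 genes higher in ST than in WT hearts at 6 months and tested in both comparisons, 1578 were lower at 8 than at 6 months, where 545 would be if the comparisons were independent. Of 2512 lower ones 1209 were higher, where 466 would be. They are not independent, since both use the same ST hearts of 6 months. The correlation of the fold changes was -0.632, and -0.469 on average in 20 simulations without any effect. The covariance was -0.247, and -0.0179 in the simulations.

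WT hearts at 6 months were set beside WT hearts at 2 months (n = 3 and 2), over names shared by both tables. Ttn, the giant sarcomere protein titin, fell by 4.35 (SE 0.064) and the calcium release channel gene Ryr2 by 1.80 (SE 0.080), while Tnnt2 rose by 1.59 (SE 0.080). The proliferation genes Mki67 (-4.08, SE 0.212) and Top2a (-3.86, SE 0.389) were lower. Uqcrb rose by 9.99 (SE 0.210). Uqcr11 was at least 1360-fold, Actg1 at least 1130-fold, Ndufb2 at least 647-fold, Sumo2 at least 574-fold and Mospd1 at least 460-fold higher at 6 months. Lower at 6 months were Gapdhl3, by at least 20300-fold, Rpph1 by at least 5250-fold, Cep295nl by at least 950-fold, Rps24-ps18 by at least 885-fold and Tas1r2 by at least 630-fold. Each bound is from a floor of 3 counts over the group. Gapdhl3 and Rps24-ps18 have names that mark possible copies, so their reads may be shared and their values are uncertain. Genes with ordinary names, such as Actg1, Uqcr11, Ndufb2, Sumo2 and Uqcrb, are no safer. Their reads may have been counted under another name in the other table, which was not tested gene by gene. The edgeR test gave 6871 of 12326 genes, 3366 higher and 3505 lower, against 4754 and 2588 with scaling by library size only, which moved the median of all genes by 0.177. Age and table, which differ in their gene names, cannot be told apart in these values.

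ST hearts of 6 months were likewise set beside ST hearts of 2 months (n = 3 and 2). Ttn fell by 4.69 (SE 0.076), Ryr2 by 1.72 (SE 0.077) and Mki67 by 2.41 (SE 0.298), and Tnnt2 rose by 2.23 (SE 0.088). Fos rose by 4.61 (SE 0.169), Egr1 by 3.96 (SE 0.164) and Rcan1 by 2.30 (SE 0.108), while Dbp fell by 1.98 (SE 0.126), Col1a1 by 2.70 (SE 0.125) and Col1a2 by 2.10 (SE 0.099). Uqcrb rose by 10.20 (SE 0.199). Ndufb2 was at least 846-fold, Sumo2 at least 657-fold, Rpl36al1 at least 552-fold and Mospd1 at least 540-fold higher. Gapdhl3 was at least 19500-fold, Rpph1 at least 3310-fold, Cep295nl at least 1010-fold and Hbbl1 at least 927-fold lower. Atp5mk had 1 and 6273 counts, a ratio of 5370 with an interval from 963 to 212000, and Actbl2 had 12934 and 2, a ratio of 7560 with an interval from 2090 to 62400. Gapdhl3, Hbbl1, Rpl36al1 and Actbl2 are uncertain in the same way, as possible copies. The genes with ordinary names are again no safer. The edgeR test gave 7409 of 12320 genes, 3741 higher and 3668 lower, with age and table again inseparable.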

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

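Tests chosen only after the result was seen are those of other cell types, of harvest conditions, of gene copies, of RT1 reads, of macrophages and of lymphocytes. The ST effect of these named genes differed between 6 and 2 months by the edgeR test of the difference itself, which is why each is listed, with the difference in log2 units: 80 of 95 genes tested. Naming genes for a change at 1 age favours such a difference, and over all genes the share was 22.2%. Pck1 and Has1 were below the filter at 2 months and Top2a at 6 months, so their ST effect at that age was not tested alone. Standard errors of the differences reached 1.3, for Msln, which had 2 counts in WT hearts at 2 months. Slc47a1 had 3 counts in WT hearts at 6 months. A more positive ST effect at 6 than at 2 months was measured for Slc47a1 (7.55), Dnah7 (5.79), Pck1 (5.52), Nppb (5.24), Egr1 (5.19), Dnah5 (4.24) and Fos (4.23). To these come Has1 (3.96), Efcab6 (3.91), Rcan1 (3.73), Thbs1 (3.47), Myh7 (3.34), Nppa (3.27) and Mt2A (3.10). The same direction held for Ccn1 (3.08), Slc4a1 (2.94), Ucp3 (2.84), Cdkn1a (2.83), Mx1 (2.82), Acta1 (2.67) and Pnpla3 (2.59). To these come Hspa1a (2.40), Myot (2.39), Bst2 (2.36), Ankrd1 (2.28), Socs3 (2.27), Top2a (2.21) and Xirp1 (2.12). Further genes in this direction were Hspb1 (2.05), Nr4a3 (2.01), Nr4a1 (1.93), Flnc (1.76), Cldn5 (1.70), Mki67 (1.65) and Ppp1r15a (1.38). To these come Ifi27 (1.33), Hsp90aa1 (1.33), Atf4 (1.23), Cox7a1 (1.20), Tap1 (1.18), Fosl2 (1.12) and Kcnk3 (1.11). The smallest such differences were those of Nlrc5 (1.08), Pfkfb2 (1.06), Pdk4 (1.05), Vegfa (1.05), Dnajb11 (0.99), Mcam (0.99) and Acta2 (0.91). To these come Gja1 (0.78), Ndufb8 (0.76), RT1-A1 (0.72), Tnnt2 (0.62), Piezo1 (0.61) and Ndufa12 (0.55).

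A more negative ST effect at 6 months was measured for Myh6 (-0.44), Ppargc1a (-0.49), Aplnr (-0.58), Col1a1 (-1.02), Tcap (-1.07), Col3a1 (-1.08) and Nr1d1 (-1.11). To these come Ezr (-1.18), Irx4 (-1.67), Kcnh2 (-1.77), Klf10 (-1.88), Cacna1h (-1.88), Bhlhe41 (-1.94) and Lrrc10 (-2.05). The remaining ones were Dbp (-2.32), Aldh1a1 (-2.59), Tet1 (-2.85), Frem2 (-3.05), Klhl33 (-3.56), Tmem63c (-3.72) and Mgst3l1 (-3.97). To these come Sec14l5 (-4.70), Adh1c (-6.31), Folr2 (-7.04) and Msln (-7.74).

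Immediate early genes were higher in ST than in WT hearts at 6 months. A difference in depth is argued against by the totals, from 6.72 to 8.49 M, with ST libraries both below and above the WT ones. All 30 members that passed still passed after every library was thinned to 1 total, but with totals this close thinning could change little. A larger share of another cell type is also argued against, since lists of other cell types reached a median of at most 0.60 (erythroid) against 2.21. Harvest at another time of day or under other conditions stays open and may account for part of it: clock output genes had a median of -1.55 and genes that peak opposite to them 0.73. Between 8 and 6 months in ST hearts these medians were 0.25 and 0.01, over members that went both ways, which decides nothing. An effect of the transgene was not tested. At 6 months 5305 genes passed in the real grouping and at most 0 in the other 9 of 10 splits, and 15 lists against at most 13, but 10 splits are too few for a share under 0.05. Only the real one of them gave as many of either. Each other split mixes WT and ST hearts in both parts, so a true difference would itself lower its count of genes.

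WT hearts of 6 and 2 months differed by at least 16-fold for 324 genes. Gene copies counted under different names could account for some of them: 7.22% of names with an ending used for copies differed so and 2.28% of other names, a ratio of 3.16 (2.87 or 6.17 under 2 other definitions tried). That ending also occurs in ordinary names such as Bcl2 and Myl2. Where the rest of the name had to be a listed gene, 14.2% of 346 names differed so and 2.3% of others, the ratio of 6.17. Names with the ending are 62 of the 324, of which 49 were lower at 6 months, and of the 262 others 116 were lower. With the stricter definition they are 49, of which 42 were lower. These counts cannot limit the part due to copies. A gene that exchanges reads with a copy may itself have an ordinary name. A loss of long transcripts in one kind of library is also open, since genes with very long messenger RNAs had a median of -1.71 in WT and -1.72 in ST hearts, but also -0.31 in ST hearts between 8 and 6 months. In these 2 comparisons 57 and 58 of the 58 genes were below 0. Ttn held 8.09% to 9.99% of counts in the 2-month libraries and 0.437% to 0.55% in all later ones, WT and ST alike. These explanations and age cannot be told apart, because each table holds 1 age.

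Of 22 antigen presentation genes tested, 10 were lower in ST than in WT hearts at 2 months. The list's camera call was lost with an estimated correlation (adjusted p = 0.619). Reads shared between RT1 copies are argued against by the members outside that family, whose median was -1.01, fewer macrophages and monocytes by their markers' median of 0.0746 (quartiles -0.27 and 0.32), and 1 library apart from the rest by a list median of at most -0.74 without each library in turn. Fewer lymphocytes stay open and may account for it: 5 markers had a median of -0.90, though 0 of them passed. An effect of the transgene or virus was not tested.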

How the results depend on the processing

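The newer quasi-likelihood method, the fit without both libraries that stand apart at 6 months (WT replicate 1 and ST replicate 2) and the fit on names with similar WT levels were chosen after seeing the data. At 2 months, 582 genes became 1019 without a filter, 355 in DESeq2, 1244 in one fit over all groups, and 271 (without WT replicate 1) to 2013 (without ST replicate 2) with each library left out. At 6 months, 5305 became 2648 with a change of at least 1.5-fold, 4139 to 5520 with a library left out, and 5744 without both libraries that stand apart. The difference of effects ranged from 1558 to 3194 with a library left out and was 2740 on names with similar WT levels. WT at 6 against 2 months ranged from 5464 to 6810, ST from 6447 to 7197, and ST at 8 against 6 months from 3964 to 5273. Where a group is left with 1 sample, it is assumed to vary like the other groups. The replicate numbers were not used as pairs: whether they pair samples is not stated, and they gave correlations of same-number deviations of 0.0712 at 2 months, from 0.0039 to 0.111 at 6 months and from 0.0378 to 0.178 at 8 against 6 months. A block for them gave 636, 5435, 2941, 6261, 6251 and 5427 genes in the order above. The newer quasi-likelihood method gave 591, 5320, 2806, 6870, 7434 and 5133.

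Lists numbered 11 at 2 months, 0 with an estimated correlation, 0 by fry and 11 to 16 with a library left out. They numbered 15 at 6 months, 2 with an estimated correlation, 20 by fry (13 of them shared) and 13 to 15 with a library left out, and 10 at 8 against 6 months, 1 with an estimated correlation, 19 by fry and 10 to 13 with a library left out. Shared genes of 2 and 6 months numbered 237, 138 in DESeq2 and 705 at an unadjusted p in both. At 2 months these named genes turned with 1 library left out, with log2 fold changes of Nppa -1.22 to 0.775, Myh7 -1.41 to 0.0995, Myh6 -0.195 to 0.114, Atp2a2 -0.0572 to 0.167, Ryr2 -0.0106 to 0.113, Gja1 -0.259 to 0.00623 and Col1a1 -0.309 to 0.0106. The cause was not tested, beyond fewer samples or genes. Of the named genes, 38 of 54 at 2 months and 63 of 70 at 6 months kept direction and side of the threshold under every alternative run, as did all 21 of ST at 6 against 2 months, 16 of WT and 34 of ST at 8 against 6 months. Of these, 7, 6, 1, 0 and 3 were not tested in every alternative, being below a filter, missing from a table or left out with their kind. The procedure recovered 74.2% of simulated 2-fold changes at 2 months.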

Other observations

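The test of a return to the WT level was chosen only after the result was seen. Ion channel genes of ST hearts at 6 months moved both ways: of 26 tested, 9 were higher and 11 lower than in WT hearts, by the edgeR test. Kcnh2, a potassium channel of repolarization, fell by 1.69 (SE 0.083) and Kcnk3, a background potassium channel, rose by 1.05 (SE 0.080). Of 37 calcium handling genes 8 were higher and 12 lower, with the T-type calcium channel gene Cacna1h at -2.10 (SE 0.0998). Neither list passed camera, with adjusted p = 0.414 and 0.599, and 40% of all genes differed at this age.

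ST hearts of 8 months were also set beside WT hearts of 6 months, which differ in age and table. By the edgeR test 4441 of 13095 genes differed, 2329 higher and 2112 lower. A return of the immediate early genes to the WT level may hold for the list on balance, whose median was 0.13, but members went both ways, 11 higher and 7 lower of 28, so the median decides nothing. Egr1 (2.19, SE 0.149), Nr4a1 (2.01, SE 0.128) and Nr4a3 (1.88, SE 0.185) remained higher than in WT hearts, as did Nppb (3.17, SE 0.188) and Myh7 (0.81, SE 0.057). Dbp remained lower (-1.67, SE 0.071), while Hspa1a stood at 0.07 (SE 0.147) and Lrrc10 at -0.1 (SE 0.0734). These genes were picked by hand, outside the rule for named genes. None of the 7 lower immediate early genes is among them. Lists of oxidative phosphorylation (72 of 79 higher, adjusted p = 9.92e-26, and adjusted p = 0.422 with an estimated correlation) and the interferon response (23 higher and 2 lower of 37, adjusted p = 1.58e-07, and adjusted p = 0.0924 with an estimated correlation) were higher. So were endothelial markers (15 of 24 higher, adjusted p = 1.05e-06, and adjusted p = 0.422 with an estimated correlation), fetal and stress genes (11 higher and 3 lower of 18, adjusted p = 2.4e-05, and adjusted p = 0.422 with an estimated correlation), heat shock genes (10 higher and 1 lower of 26, adjusted p = 0.0218, and adjusted p = 0.422 with an estimated correlation) and sarcomere genes (13 higher and 4 lower of 28, adjusted p = 0.0409, and adjusted p = 0.474 with an estimated correlation). Clock genes were lower (14 lower and 4 higher of 23, adjusted p = 1.27e-05, and adjusted p = 0.107 with an estimated correlation), as were macrophage and monocyte markers (9 of 24 lower, adjusted p = 0.00844, and adjusted p = 0.422 with an estimated correlation). The other lower lists were ion channels (12 lower and 5 higher of 26, adjusted p = 0.0093), hypertrophy and adrenergic signalling (18 lower and 5 higher of 41, adjusted p = 0.0432) and conduction system markers (4 lower and 1 higher of 11, adjusted p = 0.0459). Each of these 3 had an adjusted p = 0.422 with an estimated correlation.

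Between 8 and 6 months in ST hearts, 5115 genes passed in the real grouping and at most 0 in the other splits of the 6 samples, so that 1 of 10 splits, the real one, gave as many. For lists, 10 passed and up to 11 in another split, and 4 of 10 splits, with the real one, gave at least as many. With 10 splits no share under 0.05 can be reached. Each other split also mixes the ages in both parts, so a true difference would itself lower its count of genes.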
